A study of Mus musculus with 10 samples.

How the data were processed

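RNA was measured in whole mammary tumour tissue of mice carrying the MMTV-PyMT transgene, which drives a viral oncogene in mammary epithelium. Of the 10 libraries, 5 came from tumours with both copies of the gene for RHBDL4 knocked out and 5 from wild-type tumours, all collected 5 weeks after tumour onset. RHBDL4, the protein of the gene Rhbdd1, is a rhomboid protease of the endoplasmic reticulum membrane. Per the labels' protocols, RNA was taken from the tumours with a column kit, selected for poly(A) and made into stranded Illumina libraries. The values used are the read counts per gene that the authors deposited, 1 column per library, whole numbers that were not normalized. The submitters' processing notes name FastQC, STAR, featureCounts and DESeq2 and the mouse build GRCm39. The versions, the annotation release, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. Reads shared by overlapping genes or by near-identical copies could therefore have been split or dropped before the counts were made.

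The table held 57010 Ensembl genes, of which 52029 had a symbol in the gene name table. These took 99.66% of all counts. There were 0 count columns without a sample. Total counts ran from 25.7 to 43.3 M counts per library. Pairs of libraries of a group were checked for repeats of 1 library, and none agreed within sampling noise (chi-square per degree of freedom from 23.2 upwards). This check does not show that libraries are independent, and the closest pair, wild-type replicates 3 and 4 (Spearman's rho across genes 0.991), shares a leading number. Each library was treated as 1 replicate, with that number as an alternative unit. The batch label differed in every library. Library names began with the same number in 3 pairs (knockout replicates 3 and 4, wild-type replicates 1 and 2, and wild-type replicates 3 and 4), and the labels do not say whether that number marks an animal. Nothing else in the labels ties libraries to animals, so p-values measure the spread between these samples, part of which may be technical.

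Knockout was compared with wild type in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F-test, robust dispersions, TMM scaling and the low-count filter filterByExpr. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. Levels are CPM, the counts of a gene divided by the TMM-scaled library size in M (mega) counts, as mean ± SD over the libraries of a group. There were 35 gene lists with 738 entries, of which 725 matched by symbol, 9 by an older name and 4 not at all. They covered epithelial, stromal and immune cell types, other tissues a dissected tumour can hold, and pathways around a protease of the endoplasmic reticulum. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, adjusted over the lists. Each was tested again with an estimated correlation and with fry. Exact permutation tests were 2-sided. Gene neighbourhoods came from a GRCm38 annotation (GENCODE), which is not the build of the counts. They were used only for which genes lie near each other.

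The tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Rhbdd1, then up to 10 called genes in each direction by fold change with a mean of at least 1 CPM and no overlap between the groups. Where fewer passed, it adds up to 5 genes in that direction with the smallest p, given as not called, and up to 4 members with the smallest p of each list described. Predicted genes with a Gm or Rik name and pseudogenes were left out of the rule. The alternatives were RLE scaling, DESeq2 1.42.0, limma-voom with sample quality weights, no low-count filter, a filter of 10 counts in every library, summing libraries with the same leading number, that number as a random block, 1 surrogate variable (sva 3.50.0) and leaving out each library in turn. Further fits on the 9 libraries without wild-type replicate 5 were chosen after the data were seen, because that library stood far from the others.

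The tests were tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, drawn from the real means, dispersions and library sizes. A further 37 genes were lowered 1.5-fold as a list, and calls on them were not counted as false. Genes were drawn independently around 1 mean for all libraries, so no simulated library had the profile of wild-type replicate 5. The rates therefore do not describe counts with 1 outlying library or with correlated genes. In the simulation of all 10 libraries, over 18577 genes, edgeR recovered 2% of the 2-fold and 38% of the 4-fold changes, with 2.44% of its calls false. DESeq2 recovered 21% and 72% there, with 38.9% of its calls false. In the simulation without wild-type replicate 5, over 19016 genes, edgeR recovered 33% and 60%, with 5.05% false, and DESeq2 recovered 51% and 74%, with 28.0% false. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made the summaries and plots.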

Results

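Gene expression was profiled by poly(A) RNA sequencing in mammary tumours of MMTV-PyMT mice, a model in which a viral oncogene drives tumours of the mammary epithelium. The series compared 5 tumours labelled as knockout for the rhomboid protease RHBDL4 with 5 wild-type tumours, 5 weeks after tumour onset, and asks how their transcriptomes differ. Knockout replicates 1 to 5 held 35.0, 29.3, 27.4, 32.8 and 33.6 M counts. Wild-type replicates 1 to 5 held 32.9, 37.6, 43.3, 33.7 and 25.7 M counts. Mean depth was 31.6 ± 3.16 M counts in knockout and 34.6 ± 6.47 M counts in wild type (SD, n = 5 each), a difference within the spread between libraries (2-sided exact permutation p = 0.373). Each library carries its own batch label, numbered 1 to 10 in the order of the samples, and the labels do not say whether it marks a sequencing batch or only that order. No value within a batch can be had, so if the labels mark batches, the batch and the group cannot be told apart.

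Rhbdd1 (ENSMUSG00000026142), the gene of RHBDL4, was lower in TMM-scaled CPM in every knockout library than in every wild-type library. Its level was 17.0 ± 3.40 CPM in knockout and 35.2 ± 7.48 CPM in wild-type tumours (SD, n = 5 each), so that knockout tumours kept 48.2% of the wild-type level. Knockout replicates 1 to 5 gave 22.3, 15.1, 17.3, 13.2 and 16.9 CPM and wild-type replicates 1 to 5 gave 45.4, 38.6, 33.7, 33.5 and 25 CPM. The difference was larger than the spread between replicates in an exact permutation test that takes the libraries as independent (2-sided p = 0.00794, the smallest that 5 against 5 libraries can give). Wild-type replicate 5, the lowest wild-type library, had a TMM factor of 0.588, against 1.01 to 1.10 in the others. Per unscaled library size its Rhbdd1 level would lie within the range of the knockout libraries. The lack of overlap over all 10 libraries, and this p, therefore rest on the scaling of that library. Without it the groups did not overlap either (2-sided exact permutation p = 0.0159, the smallest possible). In edgeR the log2 fold change of -1.05 ± 0.20 (SE) did not pass the adjustment over all genes (quasi-likelihood adjusted p = 0.669). DESeq2 (adjusted p = 0.000309) and limma-voom with sample quality weights (adjusted p = 0.0360) did call it. It was not called by edgeR on sums per leading number (-0.94, adjusted p = 0.746) or by limma-voom with that number as a block (-1.01, adjusted p = 0.9998). Counts per gene do not show which part of the transcript the remaining reads came from.

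**Figure D1:**
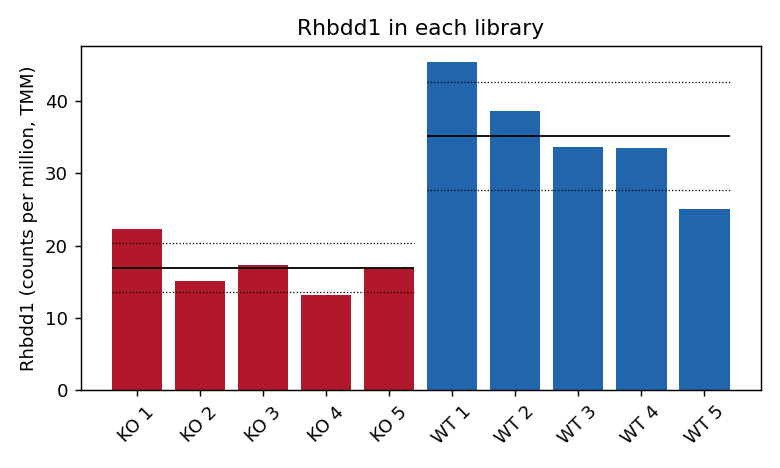
Rhbdd1 in CPM (TMM-scaled) in each library, with knockout libraries in red and wild-type libraries in blue. Solid lines are the group means and dotted lines 1 SD either side, and the highest knockout library (22.3) lies below the lowest wild-type library (25).

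Wild-type replicate 5 had a different tissue profile from the other 9 libraries. Markers of luminal epithelium, the cell layer of milk ducts and alveoli, took 0.0120% of its counts (95% Wilson interval 0.0116% to 0.0125%), against 0.624% to 0.957% elsewhere. Epcam, an epithelial adhesion protein, stood at 29.1 CPM against 1043 to 1594 CPM. Skeletal muscle genes took 11% of its counts (10.99% to 11.01%) against at most 0.217% elsewhere. Acta1, the actin of skeletal muscle, reached 48139 CPM against at most 431 CPM. Adipocyte genes took 2.19% (2.18% to 2.19%) against at most 0.406% elsewhere, and mitochondria-encoded genes 16.3% (16.31% to 16.34%) against 3.11% to 4.37% elsewhere. These intervals cover counting error only. The shares are of unscaled counts, whereas the CPM values are TMM-scaled with a factor of 0.588 in this library. That raises its CPM values, so they cannot be set against the shares. All 18 tested members of the muscle list, all 18 of the adipocyte list and all 32 of the oxidative phosphorylation list were higher there than in each of the other 9 libraries, and all 20 luminal markers were lower. The comparison was therefore also made without this library, as 1 of the fits that leave out each library in turn.

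**Figure D2:**
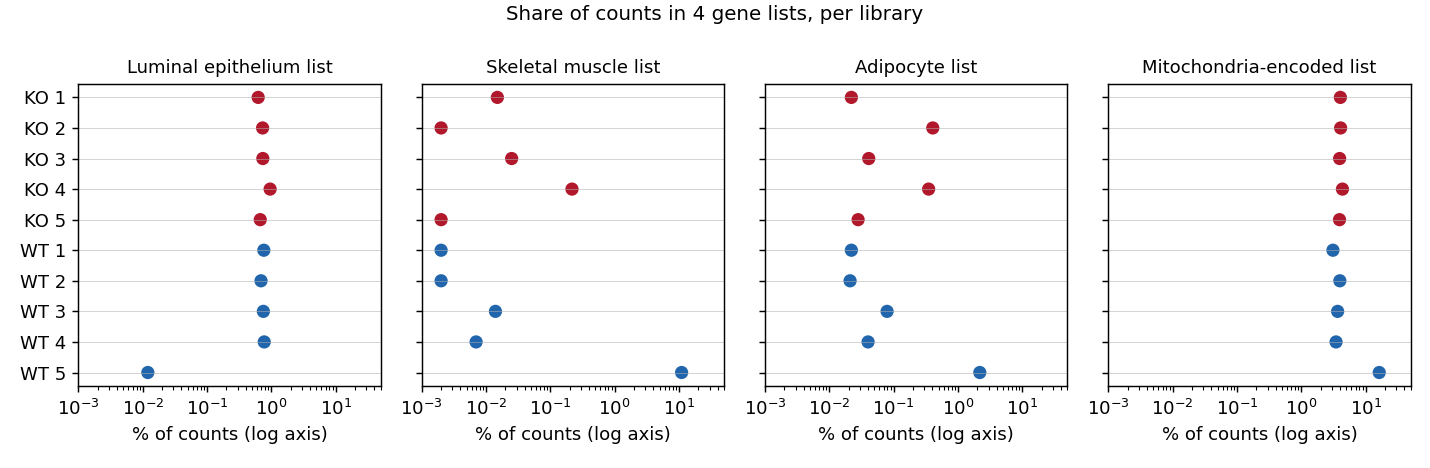
Percent of each library's counts in the luminal epithelium, skeletal muscle, adipocyte and mitochondria-encoded lists, on log axes, with knockout libraries in red and wild-type libraries in blue. Wild-type replicate 5 lies at 0.012% for the luminal list and 11% for the muscle list, apart from the other 9 libraries in all 4 panels.

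With all 10 libraries, no single gene passed the test, and the groups did not overlap for 9 of the 10 genes with the smallest p named here. Npl, an enzyme of sialic acid breakdown, stood at 81.4 ± 6.85 CPM in knockout and 44.5 ± 7.81 CPM in wild-type tumours (SD, n = 5 each), a log2 fold change of 0.87 ± 0.15. Snhg11, a long noncoding RNA, stood at 20.6 ± 6.99 against 4.78 ± 2.08 CPM, and Brinp1 at 3.26 ± 1.75 against 0.265 ± 0.277 CPM. Plekhf1 and Rpain had log2 fold changes of 0.64 ± 0.14 and 0.71 ± 0.16. In the other direction, Hspe1, a chaperonin of the mitochondrial matrix, stood at 118 ± 15.7 against 178 ± 15.9 CPM, and Chchd4, an import factor of the mitochondrial intermembrane space, at 26.4 ± 2.54 against 40.7 ± 8.07 CPM. Ung, a DNA repair glycosylase, had a log2 fold change of -0.64 ± 0.16, Lin28a of -1.64 ± 0.40 and Dysf, a membrane repair protein of muscle, of -1.42 ± 0.31. None of these 10 genes was called (edgeR quasi-likelihood adjusted p = 0.669 for each). The groups did not overlap for 369 of 18577 genes, 1.99% against the 0.794% that chance gives if the 10 libraries are independent. For these and the genes named above, whether the groups overlap can depend on the TMM factor of wild-type replicate 5 (0.588). In total edgeR called 0 of the 18577 genes, with 1301 at an unadjusted p under 0.05 where chance gives 929. Some other splits of the same 10 libraries gave more at that p, up to 2518, so this excess is not shown to be tied to the groups. With the leading number as the unit that excess was absent, with 957 of 19371 genes on sums per number (chance 969) and 313 of 18577 with the number as a block in limma-voom. Summing left 4 knockout and 3 wild-type units, 1 of them wild-type replicate 5 alone. The sums therefore mix the change of unit with fewer units and a larger weight for that library. DESeq2 called 54 (26 higher, 28 lower) and limma-voom with sample quality weights 17 (9 higher, 8 lower).

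At the level of gene groups, 7 of the 35 lists were called with the preset correlation in all 10 libraries, 4 higher and 3 lower in knockout tumours. With an estimated correlation none of the 7 was called (camera adjusted p = 0.985 for each), and fry called none (adjusted p = 0.972 for each). None of their members was called, over all genes or adjusted over the list alone. The cholesterol synthesis list was lower by -0.28 in mean log2 CPM (5.06 ± 0.22 against 5.34 ± 0.14, SD, n = 5 each), with 20 of 24 members lower (camera adjusted p = 0.000186). On this list the groups overlapped (exact permutation p = 0.0556, 0.926 adjusted over the 35 lists). Its members with the smallest p included Mvk, mevalonate kinase (7.34 ± 1.20 against 12.4 ± 3.84 CPM), and Idi1, isopentenyl-diphosphate isomerase (11.3 ± 4.74 against 23 ± 6.17 CPM). The hypoxia and glycolysis list was lower by -0.42 with 21 of 26 members lower (camera adjusted p = 0.000296), among them Pdk1 (46.3 ± 7.95 against 91.9 ± 42.9 CPM) and Ldha (1106 ± 208 against 2232 ± 1627 CPM). Ldha without wild-type replicate 5 stood at 1179 ± 225 against 1593 ± 287 CPM, a log2 fold change of -0.43 in place of -1.01. The oxidative phosphorylation list was lower by -0.51 with 32 of 32 members lower (camera adjusted p = 5.3e-06). Wild-type replicate 5 lay at 9.18 on this list against 6.68 to 6.93 in the other libraries. The luminal list was higher by 0.92 (18 of 20 members, camera adjusted p = 0.00200), the milk and alveolar list by 0.98 (20 of 24, adjusted p = 0.00359) and the ribosomal protein list by 0.25 (36 of 37, adjusted p = 5.0e-05). On these 3 lists wild-type replicate 5 lay below every other library, at 2.57, 3.48 and 8.49. Without wild-type replicate 5 the oxidative phosphorylation (camera adjusted p = 0.50), luminal (0.843), milk (0.578) and ribosomal (0.353) lists were not called. Their differences in mean log2 CPM were then -0.02, -0.02, 0.29 (15 of 24 milk members higher) and 0.06. The milk list was also not called without knockout replicate 4 (0.0937). The neutrophil list was higher by 0.75 (10 of 12 members, camera adjusted p = 0.0209), with Retnlg at 2.28 ± 3.01 against 0.250 ± 0.212 CPM. It was not called without knockout replicate 3 (adjusted p = 0.0738) or knockout replicate 4 (adjusted p = 0.194).

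Without wild-type replicate 5, genes of cell division were lower in knockout tumours. All 37 tested members of the proliferation list had negative log2 fold changes, with a median of -0.75. The list mean was 5.30 ± 0.36 log2 CPM in knockout (SD, n = 5) and 6.08 ± 0.16 in wild-type tumours (SD, n = 4). Every knockout library lay below every wild-type library on this list (exact permutation p = 0.0159, the smallest that 5 against 4 libraries can give, 0.556 adjusted over the 35 lists). Ccnb2, cyclin B2, fell to 39.0 ± 1.74 CPM from 68.3 ± 4.30 CPM, a log2 fold change of -0.81 ± 0.08 (edgeR adjusted p = 0.0372). It was the only list member called over all genes. Its call was lost when any further library was left out, and edgeR on sums per leading number and limma-voom with that number as a block called 0 genes (1044 and 1175 at an unadjusted p under 0.05). Adjusted over the list alone, 36 of the 37 members passed, all lower. Ccnb1, cyclin B1 (48.5 ± 6.63 against 92.8 ± 12.0 CPM, edgeR adjusted p = 0.110), Cdc20, an activator of the anaphase-promoting complex (54.4 ± 6.63 against 96.7 ± 12.4 CPM, adjusted p = 0.133), and Cdk1, the mitotic kinase (60.8 ± 8.52 against 106 ± 9.02 CPM, adjusted p = 0.133), were not called over all genes. With the preset correlation the list was called (camera adjusted p = 2.7e-31), but with an estimated correlation it was not (unadjusted p = 0.0281, adjusted p = 0.906), nor with fry (adjusted p = 0.110). Many other splits of the same 9 libraries also called it with the preset correlation. The lowest camera adjusted p among the other splits was 2.0e-26, with knockout replicate 1 moved to wild-type replicates 1 to 4. Knockout replicates 1 and 5 with wild-type replicates 2, 3 and 4, against the rest, gave a camera adjusted p of 7.8e-15. The real split gave the lowest of those drawn. The luminal list stood at 7.38 ± 0.28 in knockout and 7.39 ± 0.11 in wild-type libraries, a difference of -0.02 (camera adjusted p = 0.843). The adipocyte, skeletal muscle, fibroblast and endothelial lists were higher in knockout libraries in the same fit, by 1.77, 1.78, 1.21 and 0.61. With all 10 libraries the proliferation list was not called in the main fit (camera adjusted p = 0.356), and wild-type replicate 5 lay at 2.51 on it. With the preset correlation it was called lower there with DESeq2 (camera adjusted p = 0.00784), limma-voom with sample quality weights (6.3e-20) and 1 surrogate variable (7.3e-10). It was not called there with an estimated correlation (0.985), fry (0.972), or sums or blocks by leading number (0.110 and 0.719).

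**Figure D3:**
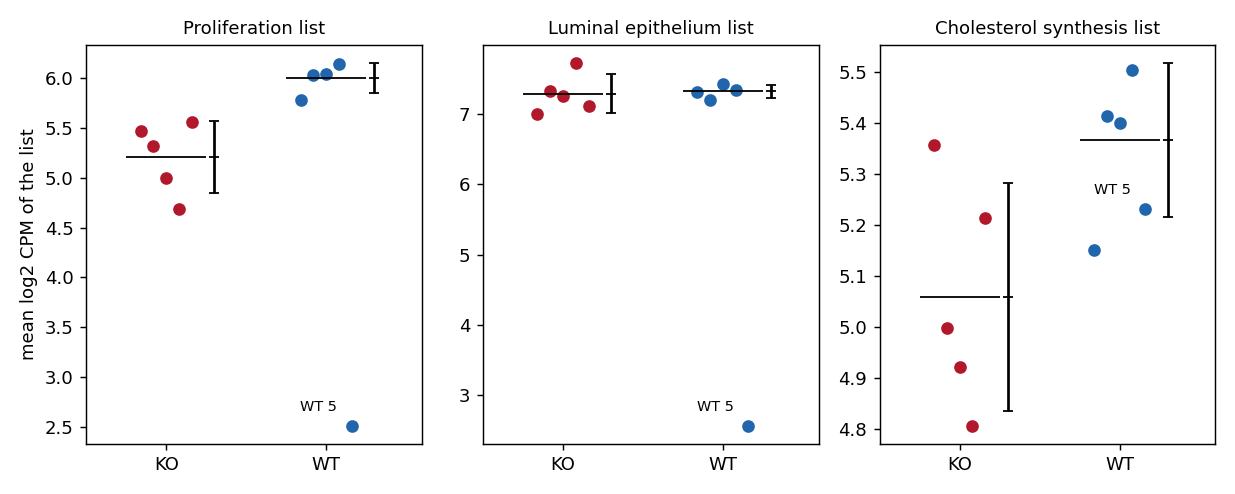
Mean log2 CPM of the proliferation, luminal epithelium and cholesterol synthesis lists in each library, scaled over all 10 libraries, with knockout in red and wild type in blue. Horizontal lines and error bars are the mean and SD over 5 knockout libraries and the 4 wild-type libraries other than replicate 5, which is marked WT 5 and lies at 2.51 on the proliferation list and 2.57 on the luminal list.

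The only other gene called without wild-type replicate 5 was Map2, which encodes a microtubule-associated protein best known from neurons. It rose to 120 ± 11.5 CPM in knockout (SD, n = 5) from 59.7 ± 6.61 CPM in wild-type tumours (SD, n = 4), a log2 fold change of 1.01 ± 0.11 (edgeR adjusted p = 0.0413). Map2 lies 16.1 Mb from Rhbdd1 on the same chromosome in GRCm38, between Rpe (15.7 Mb) and Idh1 (17.2 Mb). An antisense gene lies within Map2, and whether the counting used strand is not given in the sources used here. Npl (86.8 ± 7.27 against 50.3 ± 3.38 CPM, edgeR adjusted p = 0.0560) and Snhg11 (21.9 ± 7.47 against 5.89 ± 1.24 CPM, adjusted p = 0.138) were not called. Nor were Slc44a4, a choline-like transporter (7.81 ± 3.13 against 1.76 ± 0.41 CPM), Ankrd12 (128 ± 17.5 against 79.9 ± 10.1 CPM) and Plekhf1 (89.8 ± 11.5 against 59.4 ± 6.04 CPM). Lower in knockout tumours but not called were Cdca3, a regulator of mitotic entry (29.5 ± 1.70 against 48.2 ± 4.30 CPM, edgeR adjusted p = 0.0952), and Samm50, a component of the sorting machinery of the outer mitochondrial membrane (107 ± 8.35 against 158 ± 7.34 CPM, adjusted p = 0.133). Rhbdd1 stood at 18.1 ± 3.55 against 39.8 ± 5.64 CPM in this fit, 45.4% of the wild-type level (log2 fold change -1.14 ± 0.16, edgeR adjusted p = 0.113). Of 19016 genes tested, 2204 had an unadjusted p under 0.05 where chance gives 951, and the groups did not overlap for 1034, 5.44% against the 1.59% of chance for independent libraries. Some other splits of the same 9 libraries gave more genes at that p, up to 2894, so the excess is not shown to be tied to the groups. Neither Map2 nor Ccnb2 was called with sums or blocks by leading number, where 0 genes were called (1044 and 1175 at an unadjusted p under 0.05, where chance gives 1054 and 951). Both calls were lost when any further library was left out, with 0 genes called by edgeR in 8 of these 9 fits and only Mmrn1, named after its values were seen, without wild-type replicate 4 (log2 fold change 5.20). DESeq2 called 463 genes (179 higher, 284 lower) and limma-voom with sample quality weights 142 (47 higher, 95 lower). Both tools called Ccnb2 and Map2.

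**Figure D4:**
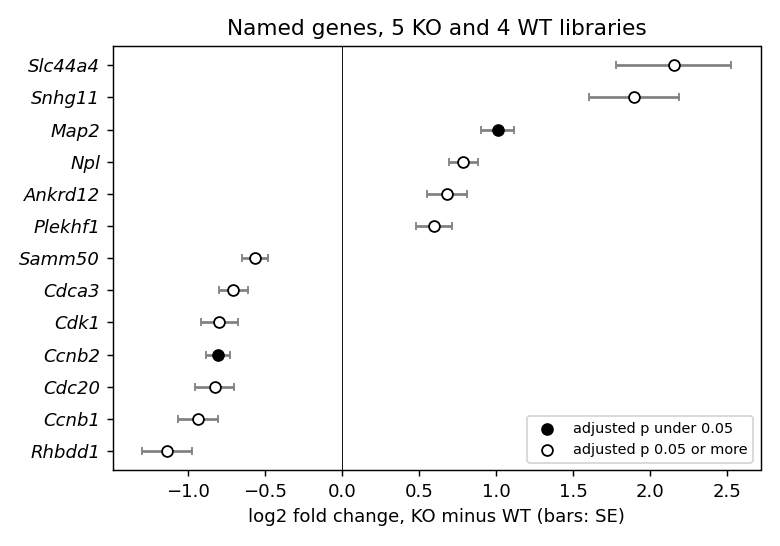
Log2 fold change of the genes named without wild-type replicate 5, knockout minus wild type, with bars of 1 SE from edgeR over 5 knockout and 4 wild-type libraries. Filled points are the 2 genes called, Map2 at 1.01 and Ccnb2 at -0.81, and open points are genes not called.

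In the fit without wild-type replicate 5, 13 lists were called with the preset correlation, 9 higher and 4 lower in knockout tumours. Other splits of the same 9 libraries gave a median of 13 called lists. None was called with an estimated correlation (adjusted p = 0.906 for each of the 13) or with fry (lowest adjusted p = 0.110). The cholesterol synthesis list was again lower, by -0.29 with 21 of 24 members lower (camera adjusted p = 2.5e-05), with Idi1 at 12.0 ± 5.04 against 26.8 ± 3.53 CPM. On this list the groups overlapped (exact permutation p = 0.0794, 0.667 adjusted over the 35 lists). The cholesterol list was 1 of 3 lists called in the same direction in both fits, with the hypoxia and glycolysis list (lower by -0.33, 22 of 26 members, camera adjusted p = 0.00329) and the neutrophil list (higher by 0.72, 9 of 13 members, adjusted p = 0.0411). The hypoxia call was lost without knockout replicate 5 (adjusted p = 0.0916) or wild-type replicate 1 (0.348). With a further library left out, the hypoxia difference ranged from -0.60 (without wild-type replicate 3) to -0.08 (without wild-type replicate 1). The neutrophil call was lost without any 1 of 7 libraries, all but knockout replicate 5 and wild-type replicate 1 (up to 0.536 without knockout replicate 4). In these fits the neutrophil difference ranged from 0.35 (without knockout replicate 4) to 1.12 (without wild-type replicate 1). The list of endoplasmic reticulum-associated degradation, a pathway in which RHBDL4 acts, was higher by 0.13 with 27 of 34 members higher (camera adjusted p = 0.0108), among them Derl1 (112 ± 16.6 against 88.5 ± 1.41 CPM) and Edem3 (74.7 ± 10.3 against 61.2 ± 6.02 CPM). It was not called without wild-type replicate 2 (adjusted p = 0.152) or 4 (0.0511). The T and NK cell list was higher by 0.53 (16 of 20 members, camera adjusted p = 0.0179), with 1 member past the test over the list alone, Il2rb, a subunit of the interleukin 2 receptor (2.78 ± 0.55 against 0.935 ± 0.367 CPM). Its mean lay near the floor, at -0.19 log2 CPM in knockout and -0.72 log2 CPM in wild-type libraries. The list was not called without knockout replicate 1 (adjusted p = 0.180), 2 (0.144) or 4 (0.0700). The mitochondria-encoded list was higher by 0.25 with all 13 members higher (camera adjusted p = 0.00123), with mt-Nd6 at 1256 ± 174 against 932 ± 139 CPM. Its smallest difference with a further library left out was 0.14, without wild-type replicate 1 (camera adjusted p = 0.0432). With all 10 libraries all 13 members were lower, by -0.41 in the list mean, and the list was not called (camera adjusted p = 0.0877).

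Lists of stromal, vascular, fat and muscle markers were higher in knockout tumours without wild-type replicate 5, and their levels were uneven among the remaining libraries. The fibroblast list was higher in knockout tumours by 1.21 (21 of 25 members, camera adjusted p = 0.0010), the endothelial list by 0.61 (21 of 21, adjusted p = 0.00222) and the mesenchymal transition list by 0.61 (14 of 20, adjusted p = 0.00935). On these 3 lists wild-type replicate 1 lay lowest. Scaled over all 10 libraries, it stood at 2.12, 1.87 and 2.67 in mean log2 CPM, against 5.30, 3.20 and 4.06 in wild-type replicate 2. Without it none of the 3 was called (adjusted p = 0.638, 0.463 and 0.463), and their differences in mean log2 CPM were 0.10, 0.15 and 0.17. The endothelial and mesenchymal calls were also lost without knockout replicate 2 (adjusted p = 0.0632 for each). The adipocyte list was higher by 1.77 (18 of 18 members, camera adjusted p = 0.00329) and the skeletal muscle list by 1.78 (18 of 18, adjusted p = 0.00549). Adipocyte shares were 0.406% and 0.350% of counts in knockout replicates 2 and 4, and the muscle share was 0.217% in knockout replicate 4. The adipocyte call was lost without knockout replicate 2 (adjusted p = 0.183), knockout replicate 4 (0.0754) or wild-type replicate 1 (0.104). The muscle call was lost without knockout replicate 4 (0.209) or wild-type replicates 1 (0.0961) or 2 (0.0778). With a further library left out, the adipocyte difference ranged from 1.02 (without knockout replicate 2) to 2.5 (without wild-type replicate 3). The muscle difference ranged from 0.70 (without knockout replicate 4) to 2.59 (without knockout replicate 5). The interferon list was lower by -0.60 (32 of 33 members, camera adjusted p = 0.0411). Scaled over all 10 libraries, wild-type replicate 1 stood at 8.26 on that list against 3.85 to 4.66 in wild-type replicates 2 to 4. Without it the difference in mean log2 CPM was 0.39 and the list was not called (camera adjusted p = 0.132). Its call was also lost without knockout replicate 1 (adjusted p = 0.0594), 2 (0.169) or 5 (0.832).

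The remaining 18 lists were called in neither fit (camera adjusted p from 0.0529 to 0.958 with all 10 libraries and from 0.300 to 0.821 without wild-type replicate 5). They were the lists of the rhomboid family, endoplasmic reticulum stress, oligosaccharyl transferase, lipogenesis, Wnt targets, EGFR and ERBB signalling, hormone-sensing, basal and keratinocyte cells, pericytes, macrophages, B and plasma cells, dendritic cells, mast cells, MHC class I, immediate early genes, red cells and Schwann cells. In the EGFR and ERBB list Tgfa, which encodes a ligand of the EGF receptor, stood at 12.9 ± 1.76 CPM in knockout (SD, n = 5) and 32.3 ± 13.2 CPM in wild-type tumours (SD, n = 4) and passed the test over the list alone but not over all genes (edgeR adjusted p = 0.205). In the rhomboid family Rhbdf1, a pseudoprotease, stood at 114 ± 18.4 against 77.5 ± 3.03 CPM and likewise passed over the list alone only (edgeR adjusted p over all genes = 0.252). Dgat1, an enzyme of triglyceride synthesis in the lipogenesis list, passed over its list alone as well. Tgfa and Dgat1 did so only without wild-type replicate 5. With all 10 libraries, 0 members of their lists passed over the list alone. In the endoplasmic reticulum stress list, Hsp90b1 stood at 605 ± 97.5 against 802 ± 117 CPM and Sdf2l1 at 40.5 ± 8.82 against 58.5 ± 11.6 CPM, and 0 members passed. For 8 lists with all 10 libraries and 6 without wild-type replicate 5, the list mean, the median fold change and the test differed in sign, and none of these was called.

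Genes close to Rhbdd1 were examined because a knockout allele can carry linked sequence from another strain. Within 10 Mb in GRCm38, 0 of 165 tested genes were called by edgeR with all 10 libraries, as among the 18411 other genes. At an unadjusted p under 0.05 they were 10 of 165 (6.06%), against 7.01% of the other genes (Fisher's exact test, 2-sided p = 0.760). Without wild-type replicate 5 they were 13 of 167 (7.78%) against 11.6% (Fisher's exact p = 0.144). DESeq2 and limma-voom also called 0 of these neighbours with all 10 libraries. Without wild-type replicate 5, edgeR called 0, DESeq2 called Agfg1 and Cnot9, and limma-voom with sample quality weights called Agfg1 and Col4a3, genes named here after their values were seen. Within 20 Mb, without wild-type replicate 5, edgeR called 1 of 265 genes, Map2, against 1 of 18750 other genes (Fisher's exact p = 0.0277). That count rests on a single gene whose call had been seen before it was made. At an unadjusted p under 0.05 the share there was 10.9% against 11.6% (Fisher's exact p = 0.847).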

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

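Of the tests in this part, the count of muscle list members and the comparison of Rhbdd1 levels for exchanged labels were chosen only after the result was seen. In 169 sets of 4 or 5 libraries of a group, 25 had 1 library far from the others by Dixon's test. Chance gives about 1 in 20, or 8.4, and 17 of the 25 were wild-type replicate 5. Values are list means in log2 CPM unless a unit is given, each with the range of the other wild-type libraries.

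Wild-type replicate 5 lay above the others on the lists of skeletal muscle (12.8, others -1.45 to 2.31), lipogenesis (9.30, others 6.41 to 6.70), oxidative phosphorylation (9.18, others 6.78 to 6.87), mitochondria-encoded genes (11.5, others 7.94 to 8.44), pericytes (6.13, others 2.78 to 3.74) and red cells (6.81, others 2.95 to 3.85). It lay below them on the luminal (2.57, others 7.20 to 7.43), proliferation (2.51, others 5.79 to 6.15), milk (3.48, others 6.57 to 7.46), ribosomal protein (8.49, others 9.47 to 9.64) and EGFR and ERBB lists (1.99, others 3.27 to 3.73). Muscle genes took 11% of its counts, adipocyte genes 2.19%, mitochondria-encoded genes 16.3%, its 10 top genes 22.5% (others 7.16% to 8.63%) and luminal genes 0.012%. Chchd4 stood there at 54.7 CPM (others 35.0 to 39.7).

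For this profile, 3 explanations were weighed. A few genes taking most of the counts is argued against, because outside the muscle, adipocyte and mitochondrial lists and the 10 top genes the luminal share was still 0.0173%, against 0.652% to 1.01% in the other 9 libraries. Labels exchanged with a knockout library is argued against too, because the highest Rhbdd1 level among knockout libraries was 22.3 CPM and the lowest among the other 4 wild-type libraries was 33.5 CPM. As a hypothesis, the piece sequenced may have held mostly muscle and fat with little tumour: 18 of 18 muscle list members were higher there than in each other library, with Acta1 at 48139, Myh4 at 25932 and Car3 at 16332 CPM. Of the 18 muscle genes, 1 is also in another list and 18 reach a mean of 1 CPM in the other 9 libraries, and an exchange with a sample from outside the series stays open.

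Wild-type replicate 1 lay above the other wild-type libraries on the MHC class I list (8.28, others 5.98 to 6.20, with all 10 libraries; 8.35, others 6.06 to 6.25, without wild-type replicate 5) and the hormone-sensing list (3.20, others 2.43 to 2.63). Wild-type replicate 2 lay above the others, without replicate 5, on the Wnt target list (5.22, others 3.73 to 3.84) and the keratinocyte list (5.95, others 0.609 to 1.41), and for Brinp1 with all 10 libraries (0.753 CPM, others 0.0858 to 0.211). Muscle genes took 0.217% of counts in knockout replicate 4 (other knockout libraries 0.002% to 0.025%). Cdca3 stood at 26.5 CPM in knockout replicate 1 (other knockout libraries 29.7 to 30.6, without wild-type replicate 5).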

How the results depend on the processing

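All alternatives on the 9 libraries without wild-type replicate 5, and the count of neighbours at an unadjusted p, were chosen after the data were seen; the others were fixed beforehand. No paired analysis was possible because no replicate number or label pairs a knockout with a wild-type library. List values are mean fitted log2 fold changes, and the cause of a change was not tested except where a sample was left out or a list was fitted with its own mean as covariate. In simulated counts edgeR recovered 2% of 2-fold and 38% of 4-fold changes with the dispersions of all 10 libraries, and 33% and 60% with those of the 9 without wild-type replicate 5.

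With all 10 libraries, DESeq2 called 54 genes and 20 lists and limma-voom with sample quality weights 17 genes, against 0 by edgeR (1301 at an unadjusted p under 0.05). Both called Rhbdd1 (log2 fold change -1.06, adjusted p = 0.000309, and -0.95, adjusted p = 0.0360). Summing libraries by leading number or adding 1 surrogate variable gave 11 lists each, and an estimated correlation or fry gave 0. At an unadjusted p under 0.05, 10 neighbours of Rhbdd1 passed (Fisher's exact p = 0.760). RLE scaling and both other filters also gave 0 genes. The direction in camera reversed for the luminal (-0.14) and milk (-0.13) lists with limma-voom weights and the adipocyte list (-1.77) with DESeq2. For the proliferation list it turned to higher on sums by leading number (camera adjusted p = 0.11) and without wild-type replicate 4 (0.969). Neither was called, and the mean log2 fold changes stayed negative (-0.18 and -0.36). On these sums wild-type replicate 5 was 1 of 3 wild-type units, so its weight grew along with the change of unit. The proliferation list was called lower with DESeq2 (camera adjusted p = 0.00784), limma-voom weights (6.3e-20) and 1 surrogate variable (7.3e-10), at mean log2 fold changes of -0.47, -0.68 and -0.44. Leaving out each library gave 0 to 2 genes, 7 to 17 lists, and ranges of 0.0407 to 0.46 for the luminal list (the lowest without wild-type replicate 5, where camera's direction reversed), -0.94 to 0.48 for the endothelial, -1.67 to 1.11 for the interferon, -1.39 to 0.25 for the mitochondria-encoded and -8.32 to 3.15 for the muscle list.

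Without wild-type replicate 5, DESeq2 called 463 genes, limma-voom weights 142 and 1 surrogate variable 11, and summing, blocking by leading number or the fibroblast mean as covariate gave 0, against 2 by edgeR (2204 at an unadjusted p under 0.05). With the adipocyte mean as covariate 3 genes were called, Ccnb2, 1700047M11Rik and ENSMUSG00000118672, the last 2 named after their values were seen. Rhbdd1 was called by DESeq2 (-1.14, adjusted p = 7.4e-07) and limma-voom weights (-0.94, adjusted p = 0.0249), and each called 2 of its neighbours (Fisher's exact p = 0.446 and 0.352). The list count was 6 with the fibroblast mean, 3 with the adipocyte mean, and 0 with an estimated correlation or fry. The direction in camera reversed for the fibroblast list with its own mean as covariate (0.0130, by construction), the endothelial list with limma-voom weights (-0.0302) and the interferon list with 1 surrogate variable (0.50) or the fibroblast mean (0.76). Leaving out each further library gave 0 to 1 genes, 7 to 13 lists and -1.91 to 0.94 for the interferon list. The cholesterol and proliferation lists were called with the preset correlation under every alternative here and lost only with an estimated correlation or fry. Neither passed the exact permutation test adjusted over the 35 lists (adjusted p = 0.667 and 0.556), and on the cholesterol list the groups overlapped.

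Among the other list values, 532 were the same, 64 passed newly, 27 no longer passed and 69 moved with all 10 libraries, and 512, 13, 87 and 48 without wild-type replicate 5. Among named genes, 164 values were the same and 14 passed newly with all 10 libraries, and 155, 24 and 25 (no longer passing) without wild-type replicate 5. No named gene reversed.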

Other observations

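Of the tests in this part, those of the luminal list, of means per leading number and of genes within 10 or 20 Mb of Rhbdd1 were chosen only after the result was seen. Hspd1 and Hspe1 encode the chaperonin and co-chaperonin of the mitochondrial matrix. In TMM-scaled CPM over all 10 libraries, both were lower in every knockout library than in every wild-type library. Hspd1 stood at 305 ± 57.7 CPM in knockout and 498 ± 91.3 CPM in wild-type tumours (SD, n = 5 each), a log2 fold change of -0.71 ± 0.18, and Hspe1 had one of -0.59 ± 0.13. Neither was called (edgeR adjusted p = 0.669 for each), and Hspd1 was named after its values were seen. Hspd1, Idh1, Map2 and Rpe lie on the chromosome of Rhbdd1, 27.3, 17.2, 16.1 and 15.7 Mb away in GRCm38.

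For the proliferation list, lower in knockout tumours without wild-type replicate 5, 2 technical explanations were weighed. Fewer tumour epithelial cells in knockout libraries is argued against, because the luminal list differed by -0.0155 in mean log2 CPM and lay above the proliferation difference by 0.759 ± 0.290 (SE). Libraries sharing a leading number cannot be told apart from the knockout: with 1 mean per number the groups did not overlap (highest knockout 5.66, lowest wild type 5.98), but 4 against 2 numbers give an exact permutation p of 0.133, the smallest possible. Adipocyte, muscle, fibroblast and endothelial lists were higher in knockout libraries (by 1.77, 1.78, 1.21 and 0.61), and with the fibroblast or adipocyte list mean as covariate the mean log2 fold change of the proliferation list was -0.82 or -0.70, against -0.75 without. As a hypothesis, knockout tumours may divide less than wild-type tumours at this time, which these data cannot separate from those open explanations.

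Other splits of the same libraries were counted for each result across many genes, 100 drawn of the 126 possible with the real one included. For the 2 genes called by edgeR without wild-type replicate 5, 1 of 100 splits, the real one, gave as many, with 1 gene as the highest of the others. Chance is still not excluded, because this fit was singled out after the data were seen and not all of the 126 splits were drawn. The count also takes the 9 libraries as independent. Summing or blocking by leading number called 0 genes (1044 and 1175 at an unadjusted p under 0.05). For the 463 genes called there by DESeq2, 7 of 100 splits gave as many (highest other 814), and for the 13 lists 60 of 100 did (highest other 19, median 13), so chance cannot be excluded for either. With all 10 libraries, the 0 genes of edgeR (1301 at an unadjusted p under 0.05; 54 called by DESeq2 and 17 by limma-voom with sample quality weights) leave nothing to test, because each of the 100 splits gives at least 0 (highest other 1). Chance cannot be excluded for the 54 genes of DESeq2 (22 of 100, highest other 577) or the 7 lists (100 of 100, highest other 26). The split with 577 genes set knockout replicates 2 and 4 and wild-type replicates 3, 4 and 5 against the other 5 libraries. These were the 5 libraries highest on the adipocyte, endothelial, macrophage, dendritic and mast cell lists. That match was looked for after the split was seen, and whether the number of calls follows these lists over splits was not tested.

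With all 10 libraries, 5 of 19 genes in the 5 Mb window that holds Map2 had an unadjusted p under 0.01, more than in any other of the 532 windows (highest other 3). That window was picked by Map2, a gene called without wild-type replicate 5. Among the 5 were Idh1 (81.7 ± 9.86 against 151 ± 52.8 CPM) and Rpe (54.5 ± 13.0 against 87.2 ± 13.9 CPM), neither called. They lie 17.2 and 15.7 Mb from Rhbdd1 in GRCm38. Chance position stays open, because 75 of 1000 shuffles gave some window with as many. Reads shared between overlapping genes cannot be told apart, because 2 of the 5 genes remained with 1 gene kept per overlapping set, as many as in 18 windows, this one included, and in 1000 of 1000 shuffles. A linked segment from another strain cannot be told apart either: the share at p under 0.05 within 10 Mb gave a Fisher's exact p of 0.760 but does not reach the window, and within 20 Mb, which does, the share was 8.20% against 6.98% (p = 0.458), and 10.9% against 11.6% without wild-type replicate 5 (p = 0.847). Without wild-type replicate 5 the window held 6 of 23 genes, Map2 among them, and 18 windows, this one included, held as many.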
